A study of Sus scrofa with 20 samples.

How the data were processed

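Deposited values were used as they stand. The log2 values were made by the authors before the files were deposited: per the submitters' processing notes, RMA and MAS5 were used, without a version or a statement of which step each served. Per the labels, total RNA was extracted with Trizol, converted to cDNA with a T7-oligo(dT) primer, labelled with biotin and hybridized to the 1-colour Affymetrix porcine array. The log base is not stated in the table and was taken as 2 from the range of the values, which carry 2 decimals. The values are not centred per gene. Versions of the upstream software, the scanner settings and the annotation release used by the submitters are not given in the sources used here, and raw image files were not used here.

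The groups, comparisons, gene lists, thresholds and alternatives were fixed before the data were examined, from the labels and the series description. The 30 lists covered chaperones and protein turnover, energy metabolism, antioxidant and late preconditioning effectors, hypoxia, apoptosis, immediate early genes, cytokines, interferon, extracellular matrix, fetal program, sarcomere, growth factors, ribosomal proteins, cell division and markers of other cell types. Of their 747 members 555 were measured, 15 of them under an older symbol. Gene symbols came from the probe table of the platform, checked against RefSeq gene identifiers for 10297 entries, of which 9989 matched. Of the tested probe sets, 10069 had 1 symbol, 198 had several and 13732 had none. A gene was represented by its probe set of highest mean signal, and 2261 of 6765 genes had more than 1 probe set.

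Group means were fitted to all 20 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, leaving 16 residual degrees of freedom, and the 6 differences between groups were tested with moderated t-statistics. A probe set passed at a Benjamini-Hochberg adjusted p below 0.05 within a comparison. Adjusted p-values of genes come from limma, and those of gene lists from camera in limma, with the preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. Counts of members adjusted over the list alone use the same p-values, adjusted within the list. Genes were named by a rule: 1 symbol that is not a locus or clone name, mean of the higher group above the 30th percentile of signal, and an adjusted p below 0.05. Against control the 12 largest differences in each direction were taken, between protocols the 8 largest, and from each list up to 4 members of smallest p that passed. The text gives a part of the named genes, not in order of size, and mostly ones that kept their calls under the alternatives. Differences between array properties were tested with two-sided exact permutation tests over all divisions of 10 arrays into 5 and 5. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

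The procedure was tried on simulated arrays of 23999 probe sets, of which 67, 67 and 66 had known differences of log2 0.5, 1 and 2. With the pooled SD, false calls made up 7.41%, 7.73% and 7.61% of calls for SWOP, RCO and RCS against control (14 of 189, 14 of 181 and 14 of 184), where 5% was aimed at. With each group's own SD they made up 8.84%, 31.2% and 8.99% (16 of 181, 80 of 256 and 16 of 178). These shares depend on how many probe sets were changed. With own SD, differences of log2 0.5, 1 and 2 were recovered in 53.73%, 95.52% and 98.48% of cases in SWOP against control, 70.15%, 94.03% and 100% in RCO, and 50.75%, 95.52% and 96.97% in RCS. Camera called 5 of 5 lists that had been shifted and 0 of 20 unchanged lists, over 6765 genes in RCS against control. The simulated genes varied independently of each other, so this does not test camera on lists whose genes vary together.

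Alternatives were quantile normalization, centring of each array on its median, leaving out dim probe sets below the 30th percentile, an intensity trend with robust spread, array weights, a replicate block, a limit of 1.5-fold, a fit of only the 2 groups compared, the correlation estimated for each list, fry, the mean of all probe sets of a gene, controls split 2 against 3, and each array left out in turn. Fits without the 2 arrays of high spike-in signal and without RCO replicates 2 and 3 were added after the data had been examined. A change of pseudocount could not apply to values already on a log2 scale. The genes run through these alternatives were at first those of called lists and were later extended to every list.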

Results

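Gene expression was measured in the heart of 20 female pigs with a 1-colour Affymetrix porcine array, 1 array per animal, in 4 groups of 5. Control animals were sham-operated. In the SWOP group the coronary artery was occluded 2 times for 10 min, each followed by 10 min of reperfusion, and the labels place sampling after 24 h of reperfusion. The RCO group received the same stimulus 6 times at intervals of 12 h. The RCS group underwent 90 min of low-flow ischemia 6 times at intervals of 12 h. The time between the last episode and sampling in RCO and RCS is not given in the sources used here. Per the series title, the question was whether preconditioning after chronic ischemia differs in its molecular mechanisms from the classical second window, the late protection that follows a brief stimulus. The values are deposited log2 signals for 24123 probe sets, of which 23999 were tested after 124 control spots were left out. All array medians lay close together. Of the tested probe sets, 10069 carried 1 gene symbol, and these stood for 6765 genes. The number of arrays limits the precision of every comparison, with a median standard error of 0.111 (log2) for a difference between 2 groups. The limma and permutation p-values measure spread between animals, since the labels and design describe 5 separate pigs per group. Camera p-values with the preset correlation set the genes of a list against the other genes, taken as nearly independent. They therefore do not measure spread between animals.

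The first principal component, with 48.9% of the variance, ran from control to RCS. Controls scored −39.9 to −26.6, SWOP −27.5 to −17.4 and RCS 26.4 to 64.3. RCO spread widely, from −18.3 to 44, with RCO replicates 2 and 3 at 44 and 29.4, among the RCS arrays. Correlations between arrays of the same group were 0.985 to 0.992 in control, 0.991 to 0.996 in SWOP, 0.959 to 0.990 in RCO and 0.987 to 0.994 in RCS. The interquartile range of log2 values was 3.09 ± 0.0455 in control, 3.28 ± 0.02 in SWOP, 3.19 ± 0.131 in RCO and 3.36 ± 0.0804 in RCS (SD, n = 5 each). It was wider than in control in SWOP and in RCS (two-sided exact permutation p = 0.00794 for each, the smallest possible with 5 against 5). The mean log2 signal of the spike-in controls, transcripts foreign to the pig that are added to each sample, was 9.99 in RCS and 10.29 in control (exact permutation p = 0.00794). The 3′ minus 5′ signal of the actin control spots, a measure of transcript integrity, was 0.652 in RCS and 1.55 in control, and that of GAPDH and EF1a differed by 0.144 and −0.122, RCS minus control (exact permutation p = 0.00794, p = 0.0238 and p = 0.0159). The actin 3′ signal itself also differed in level, with means of 12.92 in control, 13.37 in RCO and 13.93 in RCS.

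**Figure D1:**
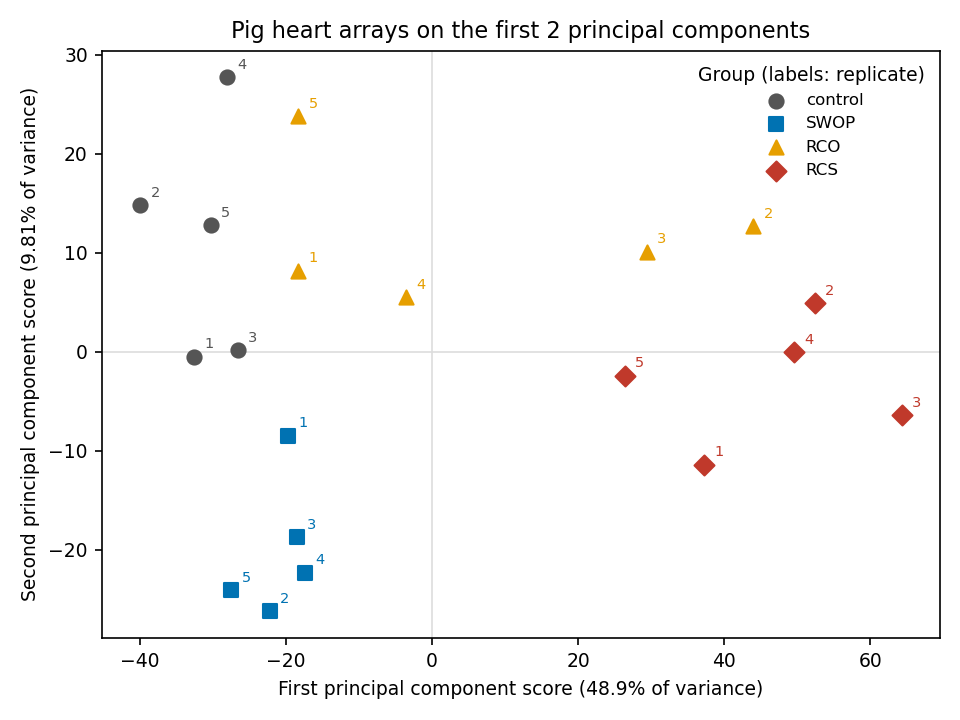
Scores of the 20 arrays on the first principal component (horizontal, 48.9% of the variance) and the second (vertical, 9.81%), without units; each point is 1 array, coloured by group. Controls lie between −39.9 and −26.6 on the first component and RCS arrays between 26.4 and 64.3, with RCO replicates 2 and 3 at 44 and 29.4.

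SWOP was compared with control to find which transcripts differ 24 h after a brief stimulus. CNN1, which encodes the smooth muscle protein calponin, was 2.81-fold higher in SWOP (log2 10.11 ± 0.39 against 8.62 ± 0.40, SD, n = 5 per group, limma adjusted p = 0.0065), and all 5 SWOP arrays exceeded every control array. LDHA, a subunit of lactate dehydrogenase, rose 1.99-fold (11.49 ± 0.15 against 10.50 ± 0.32, adjusted p = 0.0065), also in 5 of 5 arrays. ARNTL, a core activator of the circadian clock, rose 2.46-fold (adjusted p = 0.013), while the clock repressor PER1 fell 1.77-fold (adjusted p = 0.015). Both also passed against the same controls in RCO and RCS, ARNTL at log2 1.03 and 1.43 and PER1 at −0.68 and −0.64. The differences of ARNTL and PER1 are therefore not particular to SWOP. Nor is that of LDHA, which rose further in RCO and RCS (below), or that of CNN1, at 10.04 to 11.20 on the RCS arrays. CLU, which encodes the secreted chaperone clusterin, fell 2.83-fold (10.88 ± 0.57 against 12.39 ± 0.21, adjusted p = 0.0092). The transcription factor FOXO3, a regulator of stress resistance and atrophy genes, fell 1.62-fold (adjusted p = 0.0065). TNNT1, a slow skeletal troponin T, GLRX, a glutaredoxin, and SC5D, an enzyme of sterol synthesis, rose by log2 1.09 ± 0.24, 0.97 ± 0.16 and 0.94 ± 0.20 (SE, n = 5 per group). These genes kept their calls without any single array, as did HSPB6, PDE4B and PPL, whereas 38 of the 50 genes named by the rule for SWOP lost theirs at least once. Quantile normalization ended the calls of 16 of the 50. The genes given in this paragraph are ones that kept their calls in these settings, so they do not represent all 50.

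Camera called 6 of the 30 gene lists in SWOP with the preset correlation, 3 higher and 3 lower. With the correlation estimated for each list camera called 0, at an adjusted and at an unadjusted p below 0.05, and fry called 1, the hypoxia list (adjusted p = 0.022). Of 16 measured immediate early genes, transcription factors and regulators that respond within minutes to stimuli, 0 rose, 3 fell and 13 did not pass (0 and 4 adjusted over the list alone). Their mean was −0.81 (camera adjusted p = 3.6e-05, adjusted p = 0.75 with an estimated correlation). NR4A3, an orphan nuclear receptor, fell 7.1-fold (7.24 ± 0.96 against 10.07 ± 1.89, SD, adjusted p = 0.026), and FOSL2 fell by 0.94 ± 0.23 (SE, adjusted p = 0.024). On single arrays the list stood at −0.80, −0.83, 0.32, 1.35 and −0.05 in control replicates 1 to 5, and at −1.21 to −0.18 in SWOP. Control replicates 1 and 2 thus lay within the SWOP range, and fry did not call the list (adjusted p = 0.16). Without control replicate 4 the list mean was −0.47 (camera adjusted p = 0.0054, which does not measure spread between animals). FOSL2 then had an adjusted p of 0.063 and NR4A3 0.076. FOSL2 was also lost without SWOP replicate 2 (0.053), and NR4A3 without control replicate 5 (0.061) or SWOP replicates 2 (0.065), 3 (0.051), 4 (0.057) or 5 (0.068). Glucose uptake and glycolysis had 3 of 19 members higher, 0 lower and 16 that did not pass (7 and 0 adjusted over the list alone), among them LDHA (mean 0.28, camera adjusted p = 0.017, adjusted p = 0.76 with an estimated correlation). Of 58 cytosolic ribosomal proteins, 2 rose and 56 did not pass (2 adjusted over the list alone, mean 0.10, camera adjusted p = 0.017, adjusted p = 0.94 with an estimated correlation). RPL3 was one of them, at 0.69 ± 0.16 (adjusted p = 0.017, and 0.052 without control replicate 2), and the list's own call was lost without control replicate 1 (0.088) or SWOP replicate 1 (0.24), or with dim probe sets left out (0.055).

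Of 45 subunits of oxidative phosphorylation, 1 rose and 44 did not pass (0 adjusted over the list alone, mean 0.14, camera adjusted p = 0.045, adjusted p = 0.94 with an estimated correlation). That call was lost without control replicates 2 (0.10), 4 (0.12) or 5 (0.059) or SWOP replicates 2 (0.058) or 5 (0.14), after quantile normalization (mean 0.07, adjusted p = 0.12) and with dim probe sets left out (0.16). Cytokines, chemokines and adhesion molecules had 2 of 23 members lower and 21 that did not pass (2 adjusted over the list alone, mean −0.39, camera adjusted p = 0.0072, adjusted p = 0.94 with an estimated correlation). Adipocyte markers had 1 of 7 lower and 6 that did not pass (3 adjusted over the list alone, mean −0.50, camera adjusted p = 0.024, adjusted p = 0.75 with an estimated correlation). Both calls were lost without control replicate 4, at means of −0.06 (adjusted p = 0.13) and −0.19 (adjusted p = 0.12). Among the 24 lists that were not called, 4 of 23 cytosolic heat shock proteins rose (6 adjusted over the list alone, camera adjusted p = 0.23), including the small heat shock protein HSPB6 at 0.85 ± 0.19 (SE, adjusted p = 0.015). Of 31 proteasome and ubiquitin ligase genes 3 rose (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.10), and of 22 cell division genes 2 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.15). Each of the other 21 lists had at most 1 member higher and at most 1 lower, with camera adjusted p from 0.15 to 0.99. Median, mean and test differed in sign for interferon, extracellular matrix, fetal program, growth factor and macrophage lists.

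In SWOP 1716 probe sets passed limma at an adjusted p below 0.05, 722 higher and 994 lower, and 552 of 6765 genes did (315 higher and 237 lower). By more than 2-fold, 9 were higher and 9 lower, and 254 differed by at least 1.5-fold, 163 higher and 91 lower. Calls followed signal level: 12.8% were higher among the dimmest probe sets and 78.4% among the brightest, with the probe sets divided by mean signal into 3 equal parts. The share of higher calls was 42.1% as deposited and 57.2% after each array was centred on its median, and quantile normalization gave 957 calls. With dim probe sets left out 655 were higher and 648 lower. The count was 567 without control replicate 2, 480 without 4 and 903 without 5, and 660, 856, 528 and 670 without SWOP replicates 2, 3, 4 and 5. It was 5710 with array weights and 4091 with only the 2 groups fitted.

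RCO was compared with control to describe the heart after the brief stimulus had been repeated over days. HSPA6, an inducible heat shock protein, was 39.8-fold higher in RCO (log2 11.95 ± 1.66 against 6.63 ± 0.29, SD, n = 5 per group, limma adjusted p = 0.00026). Its cochaperone DNAJB1 rose 8.29-fold and HSPH1, a nucleotide exchange factor of the same machinery, rose 6.79-fold (adjusted p = 0.00034 and 1.1e-05). SPP1, which encodes the matrix protein osteopontin, rose 18.5-fold (12.13 ± 1.85 against 7.92 ± 0.86, adjusted p = 0.001), and GPNMB, a glycoprotein of macrophages, rose 8.37-fold on its brightest probe set (adjusted p = 0.0019), while of its 4 other probe sets 2 had the same sign and none passed. AGT, the angiotensin precursor, fell 3.97-fold (9.03 ± 0.80 against 11.02 ± 0.58, adjusted p = 0.0033) and CPT1B, which admits long-chain fatty acids to mitochondria, fell 2.18-fold (adjusted p = 0.0012). In each of these 7 genes all 5 RCO arrays lay beyond every control array.

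Of 23 cytosolic heat shock proteins, 6 rose in RCO, 0 fell and 17 did not pass (9 and 0 adjusted over the list alone), with a mean of 0.64 (camera adjusted p = 2e-05, adjusted p = 0.38 with an estimated correlation). On single arrays the list stood at 0.61, 0.91, 0.80 and 0.86 in RCO replicates 1, 3, 4 and 5, and at 0.03 in RCO replicate 2, within the control range of −0.08 to 0.09. Endoplasmic reticulum chaperones and genes of the unfolded protein response had 9 of 19 members higher and 10 that did not pass (16 adjusted over the list alone). MANF stood at 0.89 ± 0.13 and XBP1 at 0.68 ± 0.10 (SE; mean 0.59, camera adjusted p = 9.7e-07, adjusted p = 0.38 with an estimated correlation). Of 58 ribosomal proteins 28 rose and 30 did not pass (38 adjusted over the list alone). RPL3 stood at 0.90 ± 0.16 and RPLP2 at 0.46 ± 0.08 (mean 0.23, camera adjusted p = 1.6e-10, adjusted p = 0.49 with an estimated correlation). Cell division genes had 11 of 22 higher, 1 lower and 10 that did not pass (17 and 1 adjusted over the list alone). CKS2, a partner of cell cycle kinases, rose by 1.65 ± 0.22 and the cyclin CCND2 fell by 0.88 ± 0.13 (list mean 0.59, camera adjusted p = 3.4e-06, adjusted p = 0.38 with an estimated correlation). Macrophage and monocyte markers had 7 of 14 higher and 7 that did not pass (11 higher and 1 lower adjusted over the list alone). AIF1 stood at 1.40 ± 0.23 (mean 0.99, camera adjusted p = 9.7e-05, adjusted p = 0.38 with an estimated correlation). Of 22 interferon stimulated genes 4 rose and 18 did not pass (7 adjusted over the list alone), among them the immunoproteasome subunit PSMB8 at 1.13 ± 0.17 (mean 0.52, camera adjusted p = 0.00085, adjusted p = 0.60 with an estimated correlation). Extracellular matrix genes had 9 of 30 higher and 21 that did not pass (12 adjusted over the list alone), with the collagen COL8A1 at 1.60 ± 0.31 (mean 0.78, camera adjusted p = 0.0019, adjusted p = 0.68 with an estimated correlation). The matrix call was lost without RCO replicate 2 (mean 0.56, adjusted p = 0.053) and without RCO replicates 2 and 3 (mean 0.27, adjusted p = 0.56), where COL8A1 stood at 1.02 and GPNMB at 1.96. Without both arrays the means of other lists that kept their calls were 0.52 for macrophage markers, 0.38 for endoplasmic reticulum chaperones and 0.36 for cell division. On single arrays the macrophage list stood at 1.95 and 1.45 in RCO replicates 2 and 3 and at 0.33, 0.68 and 0.55 in replicates 1, 4 and 5.

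Fatty acid uptake and oxidation had 9 of 27 members lower in RCO, 0 higher and 18 that did not pass (14 lower adjusted over the list alone). Lipoprotein lipase, LPL, stood at −0.98 ± 0.18 and the acyl-CoA synthetase ACSL1 at −0.94 ± 0.19 (SE; mean −0.45, camera adjusted p = 1.7e-08, adjusted p = 0.38 with an estimated correlation). Of 23 sarcomere and calcium handling genes 5 fell and 18 did not pass (8 adjusted over the list alone). TCAP, a protein of the Z-disc, stood at −0.47 ± 0.08 and cardiac actin ACTC1 at −0.41 ± 0.08 (mean −0.24, camera adjusted p = 3.9e-06, adjusted p = 0.38 with an estimated correlation). The tricarboxylic acid cycle had 1 of 21 members lower and 20 that did not pass (6 adjusted over the list alone, mean −0.25, camera adjusted p = 2e-05, adjusted p = 0.51 with an estimated correlation). Its mean was −0.13 without RCO replicates 2 and 3 (adjusted p = 0.012). Adipocyte markers had 3 of 7 lower and 4 that did not pass (4 adjusted over the list alone), with CFD at −0.83 ± 0.20 (mean −0.53, camera adjusted p = 0.012, adjusted p = 0.38 with an estimated correlation), and the mean was −0.22 without control replicate 4 (adjusted p = 0.048). Oxidative phosphorylation had 2 of 45 members higher, 2 lower and 41 that did not pass (2 and 2 adjusted over the list alone, mean −0.07, camera adjusted p = 0.032, adjusted p = 0.77 with an estimated correlation). That call was lost without control replicates 1 (0.067) or 3 (0.081) or RCO replicates 2 (mean 0.02, adjusted p = 0.62) or 3 (0.18), and the direction turned to 0.11 without RCO replicates 2 and 3 together (adjusted p = 0.22). With the mean of all probe sets of a gene the adjusted p was 0.073. The mean was −0.13 without RCO replicate 1, −0.11 without RCO replicate 4, and −0.13 after quantile normalization or without the 2 arrays of high spike-in signal. The other 18 lists were not called by camera, with adjusted p from 0.056 (proteasome) to 0.98 (glycolysis, cytokines and skeletal muscle). Within them LDHA rose by 1.52 ± 0.16, the antioxidant thioredoxin TXN by 1.04 ± 0.12 and the inflammasome cytokine IL18 by 1.29 ± 0.22, and catalase, CAT, fell by 0.76 ± 0.11 (adjusted p from 4.3e-05 to 0.0021). Median, mean and test differed in sign for the glycolysis, antioxidant, cytokine, neutrophil and skeletal muscle lists.

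**Figure D2:**
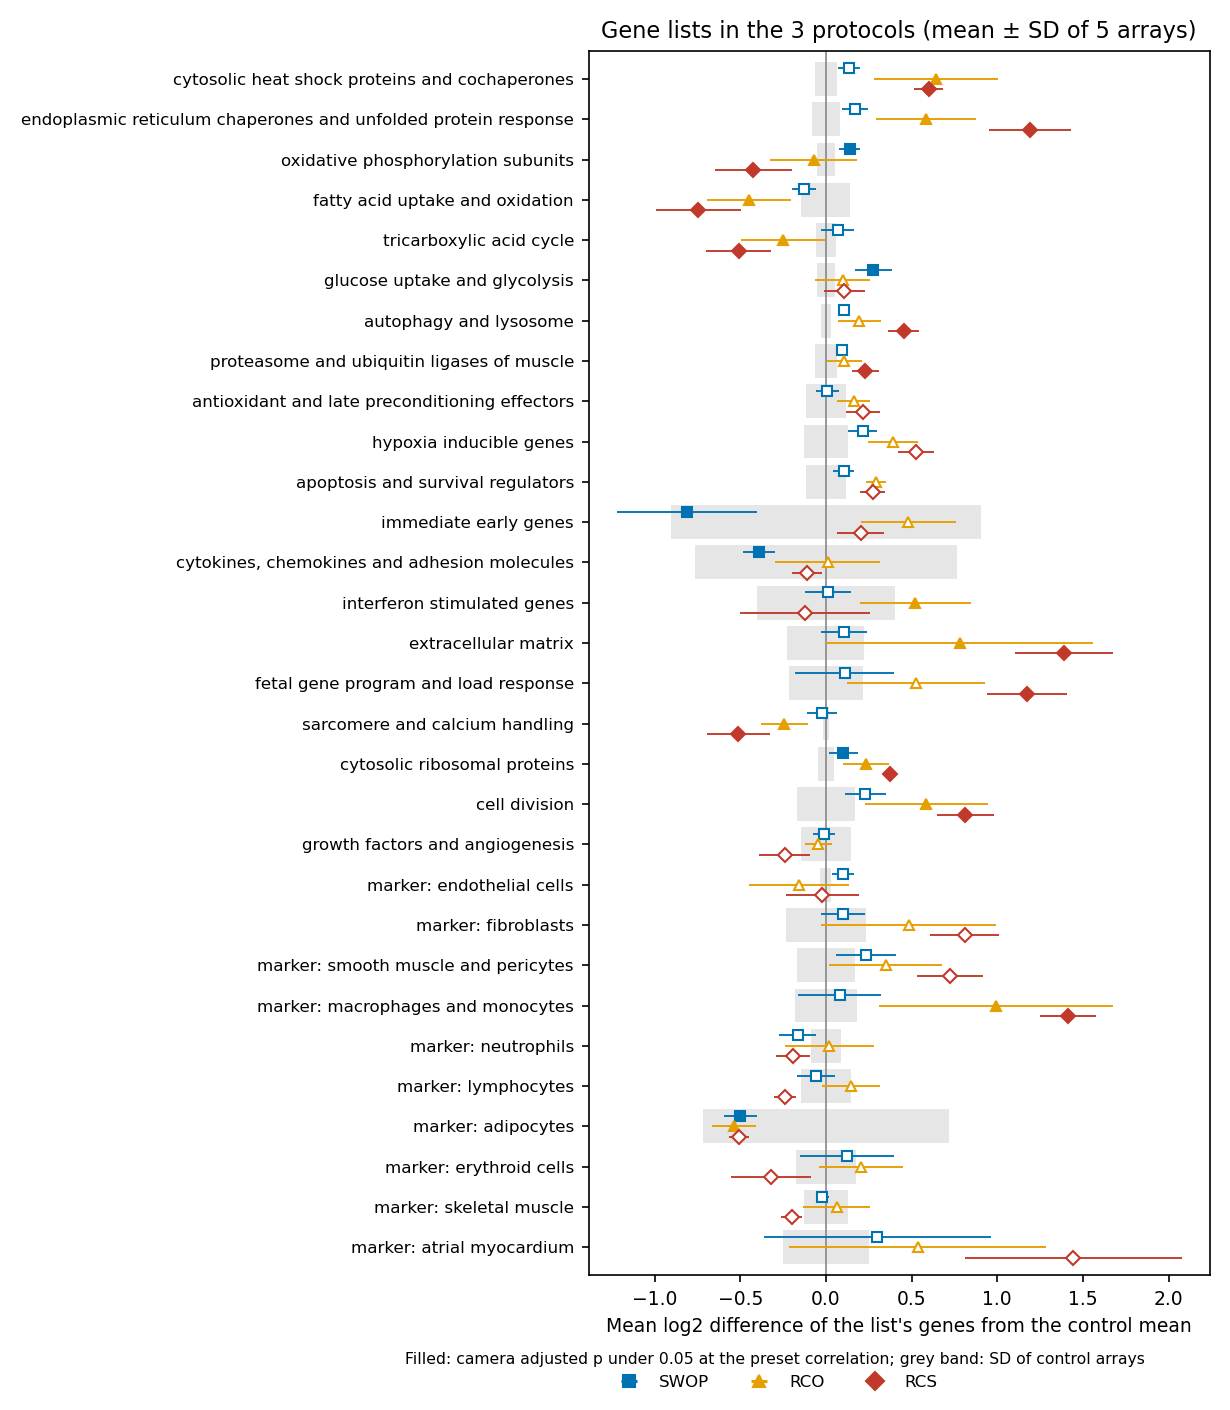
Mean log2 difference of each of the 30 gene lists (vertical axis: lists; horizontal axis: log2 difference) for SWOP, RCO and RCS against control; each point is the mean over the measured members of a list with the SD of 5 arrays, grey bands are the SD of the control arrays, and filled points mark lists called by camera with the preset correlation. Endoplasmic reticulum chaperones stand at 0.59 in RCO and 1.19 in RCS, and fatty acid uptake and oxidation at −0.45 and −0.74.

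In RCO 2571 probe sets passed limma, 1416 higher and 1155 lower, of which 228 were over 2-fold higher and 24 over 2-fold lower, and 1055 genes passed (767 higher and 288 lower). After quantile normalization the majority turned, with 1335 higher and 1481 lower. Among the dimmest probe sets 28.2% of calls were higher and among the brightest 63.7%. Camera called 12 lists, 7 higher and 5 lower, and 0 with an estimated correlation (1 at an unadjusted p below 0.05), while fry called 11. Of the 12, fry did not call interferon stimulated genes (adjusted p = 0.053), the tricarboxylic acid cycle (0.066), extracellular matrix (0.072) or oxidative phosphorylation (0.56). Fry also called hypoxia (adjusted p = 0.00025, its smallest in RCO), apoptosis (0.0017) and autophagy (0.012), which camera did not. The RCO arrays varied more than the others, and values simulated with each group's own SD gave 31.2% false calls among the calls for RCO (80 of 256). That simulation changed few probe sets, so the share does not carry over to the 2571 calls. With only the 2 groups fitted 564 probe sets passed, and 50 of the 94 genes named for RCO lost their calls. The genes given above are a part of those that kept them, so they do not represent all 94. Without RCO replicates 2 and 3 the count was 1135, and 36 of the 94 genes lost their calls. The count was 1528 without control replicate 2, 1323 without RCO replicate 3 and 4251 without RCO replicate 5.

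RCS was compared with control to describe the heart after repeated low-flow ischemia. SPP1 was 53.4-fold higher in RCS (log2 13.66 ± 0.35 against 7.92 ± 0.86, SD, n = 5 per group, limma adjusted p = 2.8e-06). LGALS3, the lectin galectin-3, rose 34.4-fold (11.38 ± 0.61 against 6.28 ± 0.14, adjusted p = 7.3e-06), and GPNMB rose 32.7-fold on its brightest probe set (adjusted p = 1.5e-06), while of 4 other probe sets of that gene 2 passed in the same direction and 1 in the opposite direction. The matrix protein tenascin C, TNC, rose 21.3-fold and NPPB, the precursor of brain natriuretic peptide, rose 13.1-fold (adjusted p = 3.1e-05 and 0.00011). KCNIP2, a subunit of the transient outward potassium channel, fell 6.97-fold and MYOM2, a protein of the sarcomeric M-band, fell 3.67-fold (adjusted p = 7.5e-05 and 6.9e-06). All 5 RCS arrays lay beyond every control array in each of these 7 genes, and each kept its call without any single array, as did 120 of the 127 genes named for this comparison.

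Camera called 13 lists in RCS, and none lost its call without a single array. With the correlation estimated for each list, each of the 13 had an adjusted p = 0.42 with an estimated correlation, so that 0 were called (1 at an unadjusted p below 0.05), and fry called 25. Of 27 genes of fatty acid uptake and oxidation 22 fell and 5 did not pass (22 adjusted over the list alone). CPT1B stood at −1.70 ± 0.18 and ECI1, an isomerase of unsaturated fatty acids, at −1.12 ± 0.15 (SE; mean −0.74, camera adjusted p = 5.5e-09, adjusted p = 0.42 with an estimated correlation). Oxidative phosphorylation had 34 of 45 subunits lower and 11 that did not pass (35 adjusted over the list alone). The complex I subunits NDUFS7 and NDUFV1 stood at −1.04 ± 0.15 and −1.04 ± 0.14 (mean −0.42, camera adjusted p = 2.8e-08, adjusted p = 0.42 with an estimated correlation). In the tricarboxylic acid cycle 18 of 21 fell and 3 did not pass (20 adjusted over the list alone), with malate dehydrogenase MDH2 at −0.69 ± 0.11 (mean −0.51, camera adjusted p = 1.2e-06, adjusted p = 0.42 with an estimated correlation). Of 23 sarcomere and calcium handling genes 20 fell and 3 did not pass (21 adjusted over the list alone). The ryanodine receptor RYR2 stood at −1.22 ± 0.19 and the sodium-calcium exchanger SLC8A1 at −1.17 ± 0.17 (mean −0.51, camera adjusted p = 5.5e-07, adjusted p = 0.42 with an estimated correlation). In the same arrays the macrophage list had a mean of 1.41, and the spike-in signal was 0.303 lower than in control.

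Of 58 ribosomal proteins 51 rose in RCS, 1 fell and 6 did not pass (52 and 1 adjusted over the list alone), with RPL3 at 1.49 ± 0.16 (SE; mean 0.38, camera adjusted p = 6.2e-11, adjusted p = 0.42 with an estimated correlation). Endoplasmic reticulum chaperones had 17 of 19 members higher and 2 that did not pass (17 adjusted over the list alone). CRELD2, a chaperone of the secretory pathway, stood at 2.35 ± 0.22 and MANF at 1.36 ± 0.13 (mean 1.19, camera adjusted p = 5.5e-09, adjusted p = 0.42 with an estimated correlation). Cytosolic heat shock proteins had 16 of 23 higher and 7 that did not pass (18 adjusted over the list alone). HSPH1 stood at 2.34 ± 0.26 and the small heat shock protein HSPB1 at 0.79 ± 0.15 (mean 0.60, camera adjusted p = 0.0013, adjusted p = 0.42 with an estimated correlation). Extracellular matrix genes had 21 of 30 higher, 3 lower and 6 that did not pass (23 and 3 adjusted over the list alone). Periostin, POSTN, stood at 3.25 ± 0.39 and the crosslinking enzyme LOXL1 at 2.37 ± 0.31 (mean 1.39, camera adjusted p = 6.3e-05, adjusted p = 0.42 with an estimated correlation). Of 14 macrophage and monocyte markers 8 rose, 1 fell and 5 did not pass (8 and 1 adjusted over the list alone). AIF1 stood at 2.12 ± 0.23 and FCER1G at 2.21 ± 0.27 (mean 1.41, camera adjusted p = 0.011, adjusted p = 0.42 with an estimated correlation). The fetal gene program and load response had 10 of 14 higher, 1 lower and 3 that did not pass (10 and 1 adjusted over the list alone). The atrial natriuretic peptide precursor NPPA stood at 3.42 ± 0.52 (mean 1.17, camera adjusted p = 0.0088, adjusted p = 0.42 with an estimated correlation). Cell division genes had 18 of 22 higher, 1 lower and 3 that did not pass (18 and 1 adjusted over the list alone, mean 0.81, camera adjusted p = 5.5e-05, adjusted p = 0.42 with an estimated correlation).

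Of 31 proteasome and ubiquitin ligase genes 18 rose in RCS, 1 fell and 12 did not pass (18 and 1 adjusted over the list alone, mean 0.23, camera adjusted p = 0.0034, adjusted p = 0.42 with an estimated correlation). Autophagy and lysosome genes had 15 of 25 higher, 3 lower and 7 that did not pass (17 and 3 adjusted over the list alone), with the lysosomal protease CTSD at 2.05 ± 0.23 (SE; mean 0.45, camera adjusted p = 0.0095, adjusted p = 0.42 with an estimated correlation). Both calls were lost after quantile normalization (adjusted p = 0.051 each, means 0.11 and 0.34). The other 17 lists were not called. In the hypoxia list 7 of 12 members rose and 1 fell (7 and 1 adjusted over the list alone), among them HIF1A at 0.68 ± 0.10. Camera gave this list an adjusted p of 0.10, whereas fry called it (adjusted p = 1.6e-06). In glycolysis 4 of 19 rose and 5 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.80), with LDHA at 2.17 ± 0.16 and the insulin-responsive glucose transporter SLC2A4 at −0.92 ± 0.19. Fibroblast markers had 6 of 11 higher and 1 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.11). Smooth muscle markers had 4 of 8 higher and 2 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.19), and endothelial markers 1 of 12 higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.76). Lymphocyte markers had 4 of 12 lower (camera adjusted p = 0.067), adipocyte markers 4 of 7 (0.053), skeletal muscle markers 5 of 9 with 1 higher (0.10), erythroid markers 2 of 4 (0.22) and neutrophil markers 1 of 6 (0.22), and each of these counts was the same adjusted over the list alone. Antioxidant and late preconditioning effectors had 9 of 25 higher and 5 lower (9 and 6 adjusted over the list alone, camera adjusted p = 0.65). Apoptosis regulators had 6 of 17 and 3 (6 and 4 adjusted over the list alone, 0.24), and cytokines 5 of 23 and 5 (5 and 5, 0.76). Immediate early genes had 2 of 16 and 2 (1 and 1, 0.95), interferon stimulated genes 1 of 22 and 2 (1 and 0, 0.43), growth factors 1 of 14 and 6 (1 and 6, 0.16) and atrial markers 2 of 4 and 0 (2 and 0, 0.28). Median, mean and test differed in sign for the glycolysis, immediate early and cytokine lists.

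In RCS 11404 of 23999 probe sets passed limma (47.5%), 4632 higher and 6772 lower, of which 955 were over 2-fold higher and 236 over 2-fold lower, and 3689 genes passed (1949 higher and 1740 lower). Calls followed signal level here too, with 19.5% higher among the dimmest probe sets and 58.8% among the brightest. The count lay between 9439 and 11417 without any single array.

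RCO was compared with SWOP to set the repeated stimulus against the single session. Because the sampling time of RCO is not given, this comparison cannot separate repetition from time since the last stimulus. HSPA6 was 42.9-fold higher in RCO than in SWOP (log2 11.95 ± 1.66 against 6.52 ± 0.62, SD, n = 5 per group, limma adjusted p = 0.00024), and DNAJB1 and HSPH1 were 10-fold and 6.22-fold higher (adjusted p = 0.00024 and 4.7e-05). NR4A3 was 16.6-fold higher and ATF3, a stress-induced transcription factor, 14.8-fold higher (adjusted p = 0.0037 and 0.001). CITED2, a transcriptional coregulator that restrains HIF1A, was 2.42-fold lower and ACSL1 2.14-fold lower (adjusted p = 0.00019 and 0.0028). In each of these 7 genes all 5 RCO arrays lay beyond every SWOP array.

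Camera called 16 lists between RCO and SWOP, 10 higher and 6 lower in RCO, and fry 6. Of the 16 calls of camera, 11 were lost with fry. With the correlation estimated for each list 0 were called at an adjusted or an unadjusted p below 0.05, and each of the 16 had an adjusted p = 0.49 with an estimated correlation. Immediate early genes, which respond to recent stimuli, had 8 of 16 higher (9 adjusted over the list alone, mean 1.29, camera adjusted p = 2.9e-06), and the unknown sampling time applies to these too. Macrophage markers had 7 of 14 higher (9 adjusted over the list alone, mean 0.91, camera adjusted p = 2.9e-06), including AIF1 at 1.12 ± 0.23 and CD86 at 0.81 ± 0.15 (0.71 and 0.53 without RCO replicates 2 and 3). Endoplasmic reticulum chaperones had 7 of 19 higher (11 adjusted over the list alone, camera adjusted p = 3.3e-05) and heat shock proteins 5 of 23 with 1 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.0031). Interferon stimulated genes had 4 of 22 higher (6 adjusted over the list alone, camera adjusted p = 2.2e-05), and extracellular matrix 4 of 30 with 1 lower (10 and 1, 0.00016). Ribosomal proteins had 5 of 58 higher with 1 lower (12 and 1, 3.8e-06) and cell division 2 of 22 (7, 0.00017). Fatty acid uptake and oxidation had 8 of 27 lower in RCO (12 adjusted over the list alone, camera adjusted p = 6.9e-06), with CPT1B at −0.89 ± 0.18 and LPL at −0.87 ± 0.18. The tricarboxylic acid cycle had 5 of 21 lower (16, 1.1e-06), oxidative phosphorylation 2 of 45 (2, 2.9e-06) and sarcomere and calcium handling 6 of 23 (8, 3.8e-05), with the calcium-binding protein HRC at −0.73 ± 0.13. Cytokines (1 of 23 higher, camera adjusted p = 0.0035) and lymphocyte markers (0 of 12, 0.012) lost their calls without RCO replicate 2 (0.062 and 0.084), and glycolysis (1 of 19 higher and 3 lower, 0.011) and endothelial markers (2 of 12 lower, 0.012) without RCO replicate 1 (0.077 and 0.22). Adjusted over the list alone these 4 lists had 5, 3, 2 with 5 lower, and 2 lower members. Without RCO replicates 2 and 3 together 7 of the 16 calls were lost: endoplasmic reticulum chaperones (0.051), oxidative phosphorylation (0.41), glycolysis (0.083), cytokines (0.25), extracellular matrix (0.65), cell division (0.30) and lymphocytes (0.054). Of the calls that held without both arrays, the means were 0.44 for macrophage markers (0.91 with them), −0.18 for fatty acid uptake and oxidation (−0.32), −0.19 for the tricarboxylic acid cycle (−0.32) and −0.14 for sarcomere and calcium handling (−0.22). The oxidative phosphorylation mean was −0.12 without RCO replicate 2 (−0.21 with it). The lymphocyte call was also lost after quantile normalization (0.066), and the endothelial call without RCO 1 and SWOP 1, the 2 arrays of high spike-in signal (0.20).

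Between RCO and SWOP 2414 probe sets passed limma, 900 higher and 1514 lower in RCO, and 808 genes (375 and 433). At 1.5-fold or more 379 were higher and 393 lower, and over 2-fold 137 and 30. Higher calls made up 58.7% among the dimmest and 26.1% among the brightest probe sets. With only the 2 groups fitted 863 passed, and 38 of the 77 genes named for this comparison lost their calls, as did 44 without RCO replicates 2 and 3. The genes given above are a part of those that kept them, so they do not represent all 77. The count was 1376 without RCO replicate 3, and 1093, 1369, 1375 and 1006 without SWOP replicates 2, 3, 4 and 5.

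RCS was compared with SWOP to set repeated low-flow ischemia against the single session, again without a known sampling time for the repeated protocol. The RCS arrays also differed from the SWOP arrays in spike-in signal (−0.261, exact permutation p = 0.0159) and in actin 3′ minus 5′ signal (−0.814, exact permutation p = 0.00794), beside all lists given here. The same measure of GAPDH went the other way (0.162, exact permutation p = 0.0238), and that of EF1a was at −0.176 (exact permutation p = 0.00794). SPP1 was 32.4-fold higher in RCS (log2 13.66 ± 0.35 against 8.64 ± 0.96, SD, n = 5 per group, limma adjusted p = 2.3e-05), LGALS3 27.4-fold and CPM, a membrane-bound carboxypeptidase, 12.4-fold higher (adjusted p = 3.1e-05 and 4.1e-06). ADHFE1, a mitochondrial hydroxyacid-oxoacid transhydrogenase, was 5.7-fold lower and AGT 5.33-fold lower (adjusted p = 1.3e-05 and 0.00013), and all 5 RCS arrays lay beyond every SWOP array in each of these 5 genes. Of 45 oxidative phosphorylation subunits 42 were lower in RCS (45 adjusted over the list alone, mean −0.56, camera adjusted p = 4.1e-15, adjusted p = 0.43 with an estimated correlation), with NDUFS7 at −1.05 ± 0.15. The tricarboxylic acid cycle had 21 of 21 lower (21 adjusted over the list alone, camera adjusted p = 2.3e-09), fatty acid uptake and oxidation 22 of 27 (22 lower and 1 higher adjusted over the list alone, camera adjusted p = 4.5e-09), sarcomere and calcium handling 17 of 23 (18 adjusted over the list alone, camera adjusted p = 1.1e-07), and each of these lists had an adjusted p = 0.39 with an estimated correlation. Endoplasmic reticulum chaperones had 16 of 19 higher (17 adjusted over the list alone, camera adjusted p = 1.4e-10), with the oxidase ERO1A at 1.36 ± 0.12, autophagy genes 11 of 25 with 3 lower (14 and 4, 0.0092) and the fetal program 9 of 14 with 1 lower (10 and 1, 0.0012), also with an adjusted p = 0.39 with an estimated correlation. Ribosomal proteins had 44 of 58 higher (48 adjusted over the list alone, camera adjusted p = 1.4e-10), extracellular matrix 21 of 30 with 1 lower (22 and 1, 3.6e-07), cell division 14 of 22 (17 with 1 lower, 4.2e-05) and macrophage markers 9 of 14 (9 with 1 lower, 0.0011), with an adjusted p = 0.43 with an estimated correlation for each. Heat shock proteins had 11 of 23 higher (12 adjusted over the list alone, camera adjusted p = 0.0092), immediate early genes 7 of 16 (8, 0.0092) and proteasome genes 5 of 31 with 1 lower (5 and 1, 0.028), each with an adjusted p = 0.51 with an estimated correlation, and the proteasome call was lost without RCS replicate 3 (0.066). Between RCS and SWOP 6989 probe sets passed limma, 3310 higher and 3679 lower, and 2571 genes (1373 and 1198). At 1.5-fold or more the majority turned, with 1725 higher and 1251 lower. Camera called 14 lists, and 0 with an estimated correlation (1 at an unadjusted p below 0.05), while fry called 23.

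RCS was compared with RCO to set the kinds of repeated ischemia side by side, with neither sampling time given. Spike-in signal and actin 3′ minus 5′ signal differed too, by −0.353 and −0.496, RCS minus RCO (exact permutation p = 0.00794 for each), beside all lists of this comparison. The same measure of GAPDH and EF1a differed by 0.126 and −0.048, which did not pass (exact permutation p = 0.111 and 0.222). TCN1, a vitamin B12 binding protein, was 7.41-fold higher in RCS than in RCO (log2 8.11 ± 0.82 against 5.22 ± 0.47, SD, n = 5 per group, limma adjusted p = 3.9e-05), and SMPDL3A, a phosphodiesterase made by macrophages, 6.71-fold higher (adjusted p = 0.00086), each with all 5 RCS arrays above every RCO array. The RCO mean of TCN1 was dim, close to the lower quartile of the RCO arrays (5.08 to 5.21), so the size of its fold is uncertain. NPPA was 4.76-fold higher (adjusted p = 0.0083), in 4 of 5 arrays beyond the RCO range. MYL1, a fast muscle myosin light chain, was 3.7-fold lower and UBD, an interferon-inducible ubiquitin-like protein, 3.55-fold lower (adjusted p = 0.0053 and 0.0032), in 5 and 4 of 5 arrays.

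Interferon stimulated genes had 0 of 22 higher and 9 lower in RCS than in RCO, with 13 that did not pass (15 lower adjusted over the list alone). XAF1 stood at −1.14 ± 0.24 and IFI44L at −0.86 ± 0.22 (SE; mean −0.65, camera adjusted p = 6.2e-06, adjusted p = 0.48 with an estimated correlation). Against the control mean the interferon list stood at 0.48 in RCS replicate 1 and at −0.48 to −0.03 in the other RCS arrays. It stood at −0.04 in RCO replicate 1 and at 0.55 to 0.74 in the other RCO arrays. Lymphocyte markers had 7 of 12 lower (8 adjusted over the list alone), including the T cell receptor subunit CD3G at −0.68 ± 0.13 (mean −0.39, camera adjusted p = 0.00013, adjusted p = 0.38 with an estimated correlation). Endoplasmic reticulum chaperones had 14 of 19 higher (15 with 1 lower adjusted over the list alone), with CRELD2 at 1.30 ± 0.22 and HYOU1 at 1.07 ± 0.18 (mean 0.60, camera adjusted p = 4.8e-08, adjusted p = 0.38 with an estimated correlation). Autophagy and lysosome genes had 8 of 25 higher with 1 lower (11 and 1 adjusted over the list alone), with CTSD at 1.54 ± 0.23 (camera adjusted p = 0.0044, adjusted p = 0.38 with an estimated correlation). Oxidative phosphorylation had 24 of 45 lower (35 adjusted over the list alone, mean −0.35, camera adjusted p = 2.8e-11), fatty acid uptake and oxidation 8 of 27 (15, 3.5e-05), with CPT2 at −0.61 ± 0.11. Sarcomere and calcium handling had 7 of 23 lower (8, 4e-04), with SLC8A1 at −0.73 ± 0.17, and the fetal program 5 of 14 higher (8, 0.0046). Each of these 4 lists had an adjusted p = 0.48 with an estimated correlation. The tricarboxylic acid cycle had 7 of 21 lower (9 adjusted over the list alone, camera adjusted p = 0.00027) and extracellular matrix 5 of 30 higher (5, 0.00032), each with an adjusted p = 0.53 with an estimated correlation. The matrix mean of 0.61 was 0.35 without RCO replicate 1, also without the 2 arrays of high spike-in signal, and 1.12 without RCO replicates 2 and 3, where the oxidative phosphorylation mean was −0.53. Ribosomal proteins had 9 of 58 higher (8 adjusted over the list alone, camera adjusted p = 1.2e-05) and proteasome genes 6 of 31 (6, 0.012), each with an adjusted p = 0.55 with an estimated correlation, and the proteasome call was lost without RCO replicate 2 (0.13) or without RCO replicates 2 and 3 (0.13).

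Cell division genes had 3 of 22 higher in RCS than in RCO (3 adjusted over the list alone, camera adjusted p = 0.046, adjusted p = 0.68 with an estimated correlation), a call lost without RCO replicates 1 (0.27) or 5 (0.23) or RCS replicates 3 (0.14) or 4 (0.078). Skeletal muscle markers had 3 of 9 lower (3 adjusted over the list alone, camera adjusted p = 0.012) and erythroid markers 1 of 4 (2, 0.047), each with an adjusted p = 0.48 with an estimated correlation. The erythroid call was lost without RCO replicates 1 (0.086), 2 (0.075) or 3 (0.052) or RCS replicates 3 (0.067), 4 (0.063) or 5 (0.099). Quantile normalization ended the calls of the cell division (0.060), erythroid (0.068) and skeletal muscle (0.063) lists. Leaving out dim probe sets (0.084 and 0.065) or the 2 arrays of high spike-in signal (0.29 and 0.060) ended the cell division and erythroid calls. The erythroid call was also lost with the mean of all probe sets (0.056) and without RCO replicates 2 and 3 (0.085). Heat shock proteins were not called (3 of 23 higher, 3 adjusted over the list alone, median 0.04, mean −0.04, camera adjusted p = 0.74), nor were macrophage markers (6 of 14 higher and 1 lower, 6 and 3 adjusted over the list alone, camera adjusted p = 0.40). Against the control mean the macrophage list stood at 1.15 to 1.56 on the RCS arrays. It stood at 1.95 and 1.45 in RCO replicates 2 and 3 and at 0.33, 0.68 and 0.55 in RCO replicates 1, 4 and 5.

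Between RCS and RCO 4572 probe sets passed limma, 2099 higher and 2473 lower in RCS, and 1463 genes (793 and 670). At 1.5-fold or more the majority turned, with 736 higher and 337 lower, and over 2-fold 184 were higher and 45 lower. It also turned with dim probe sets left out (1770 higher and 1531 lower), and median centring gave 2199 and 2196. Higher calls made up 23.9% among the dimmest and 66.4% among the brightest probe sets. Camera called 15 lists, 7 higher and 8 lower, and 0 with an estimated correlation (3 at an unadjusted p below 0.05), while fry called 12. Of the 15 calls of camera, 5 were lost with fry. With only the 2 groups fitted 931 probe sets passed, and 64 of the 92 genes named for this comparison lost their calls. The genes given above are a part of those that kept them, so they do not represent all 92. Without RCO replicates 2 and 3 the count was 9052. The count was 2945 without RCO replicate 1, 7448 without 2, 3049 without 4 and 2410 without 5, and 2053 without RCS replicate 3.

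**Figure D3:**
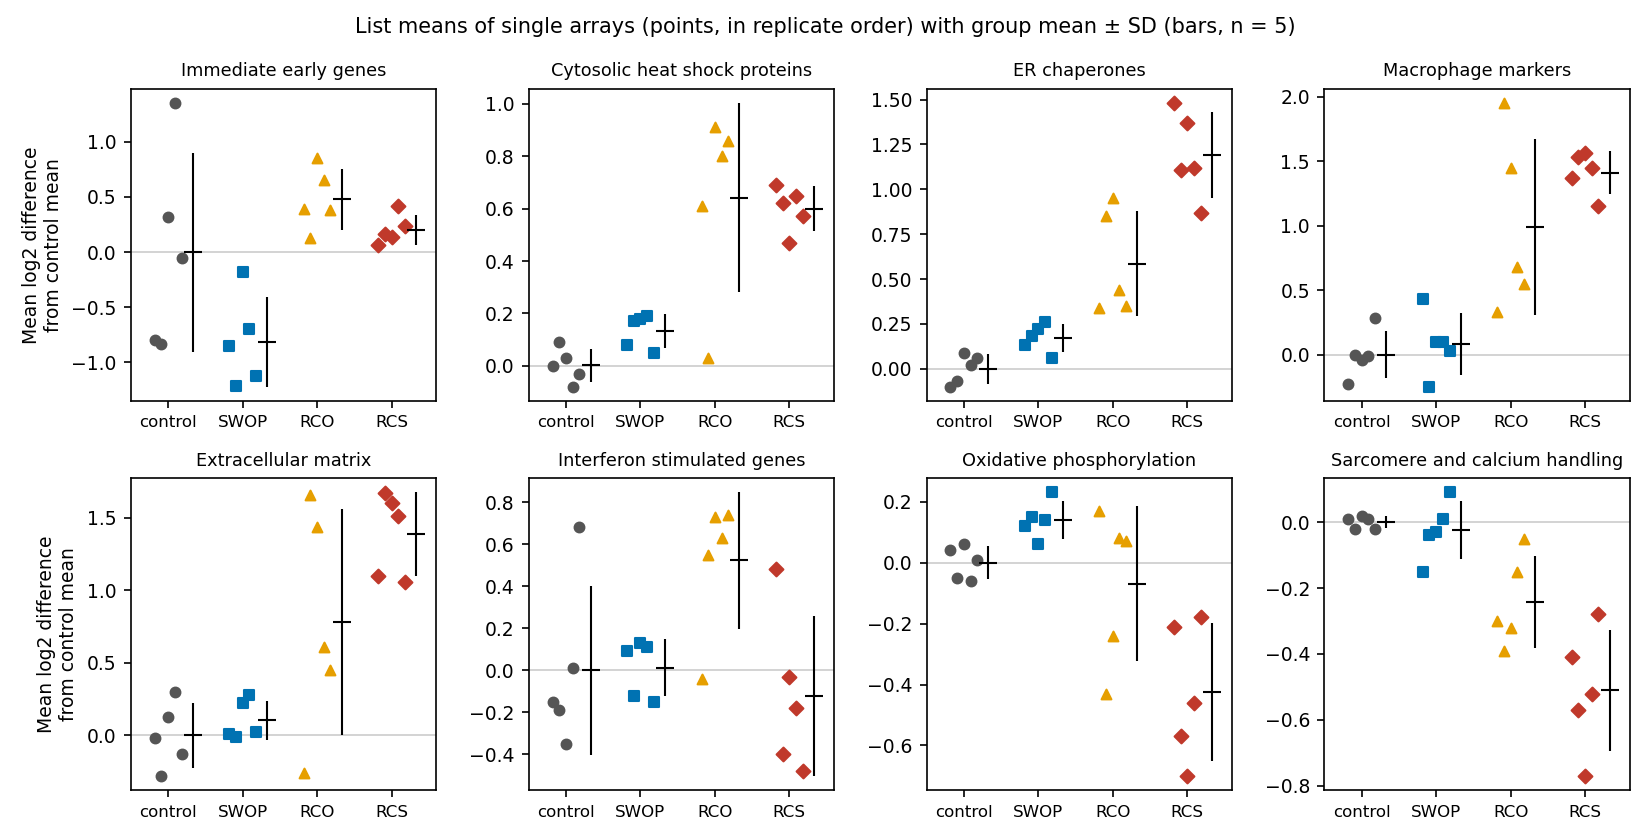
Mean log2 difference from the control mean (vertical axis) of 8 gene lists on each array; each point is 1 array, arranged on the horizontal axis by group, and bars are group means ± SD (n = 5). For extracellular matrix, RCO replicates 2 and 3 stand at 1.66 and 1.44, within the RCS range of 1.06 to 1.67, while RCO replicate 1 stands at −0.26.

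The 3 comparisons with control share their controls, so chance in the control arrays alone moves them together. SWOP and RCO shared 444 called probe sets in the same direction, against 42.6 higher and 47.8 lower for independent calls, and 2 in opposite directions. Across probe sets, which are not independent replicates, their differences correlated at r = 0.442. Simulated arrays with no group effect gave a mean of 0.497 and at most 0.886. RCO and RCS shared 2258 (273 and 326 for independent calls) with 2 opposite and r = 0.824, against a simulated mean of 0.487 and maximum of 0.876. SWOP and RCS shared 1320 (139 and 280) with 19 opposite, and 744 after quantile normalization. Their r was 0.468, against a simulated mean of 0.464 and maximum of 0.865. In each pair r thus lay below the highest simulated value. The simulated arrays shared 0 calls in 100 draws, but without a group effect they had hardly any calls to share, so this 0 says little. The covariance of the differences exceeded the simulated mean by 0.0205 for SWOP and RCO, 0.0461 for SWOP and RCS and 0.121 for RCO and RCS. With the 5 controls divided so that each comparison had its own, 20 divisions gave medians of 17 (0 to 111), 98 (0 to 905) and 681 (82 to 1169) shared calls, in the order SWOP with RCO, SWOP with RCS and RCO with RCS. The medians of r were 0.284, 0.348 and 0.722 in that order. Each comparison then had only 2 or 3 controls, so fewer probe sets could pass and r carried more noise. The fall from the full values therefore does not show how much came from the shared controls.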

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

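Of 368 groups of 5 values (array properties, list means and named genes) examined for a single array far from the other 4, 24 held one, where chance alone gives about 1 in 20. The cause of these was not tested. All values here are log2 signals for genes and spike-ins, and log2 differences from the control mean for lists. SWOP replicate 1 and RCO replicate 1 had the highest spike-in signals, 10.59 against 10.12 to 10.22 in the other SWOP arrays and 10.76 against 10.19 to 10.27 in the other RCO arrays.

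In control replicate 4 the cytokine list stood at 1.32 and the other controls at −0.49 to 0.01. The adipocyte markers of the same array stood at 1.24 against −0.52 to −0.09, and its scavenger receptor SCARA5 at 9.87 against 8.38 to 8.71. In control replicate 5 the lymphocyte markers stood at 0.25 against −0.11 to −0.02.

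In SWOP replicate 1 the proteasome list stood at 0.16 against 0.07 to 0.09, and HSPA6 at 7.59 against 6.03 to 6.46. In SWOP replicate 5 the autophagy list stood at 0.06 against 0.11 to 0.13.

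In RCO replicate 1 the interferon list stood at −0.04 against 0.55 to 0.74, the endothelial markers at −0.67 against −0.10 to 0.01, and the erythroid markers at 0.64 against 0.03 to 0.15. SMPDL3A, a phosphodiesterase made by macrophages, stood at 5.55 in that array against 7.64 to 7.91. In RCO replicate 2 the neutrophil markers stood at 0.48 against −0.13 to −0.04, the lymphocyte markers at 0.44 against 0.02 to 0.13, and the skeletal muscle markers at −0.27 against 0.09 to 0.23. DNAJB1 stood at 9.76 in RCO replicate 2 against 11.77 to 12.37. In RCO replicate 3 NPPB stood at 12.91 against 10.79 to 11.28.

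In RCS replicate 1 CNN1 stood at 10.04 against 10.90 to 11.20, CILP, a cartilage matrix protein also made by cardiac fibroblasts, at 11.11 against 12.29 to 12.46, and CLU at 12.90 against 12.48 to 12.56. PSPH, an enzyme of serine synthesis, stood at 8.07 in the same array against 7.23 to 7.29. In RCS replicate 2 the adipocyte markers stood at −0.40 against −0.54 to −0.52, and in RCS replicate 5 MYO5B, an unconventional myosin, stood at 5.26 against 4.64 to 4.81.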

How the results depend on the processing

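The fits without the 2 arrays of high spike-in signal and without RCO replicates 2 and 3 are the tests chosen only after the result was seen, and a change of pseudocount was not run because the values are already log2. Counts are probe sets that passed limma unless lists are named, and the cause of each shift was not tested. Quantile normalization gave 957 in SWOP against control and 744 shared between SWOP and RCS, and array weights gave 5710 in SWOP. At least 1.5-fold left 254, 946 and 3695 in SWOP, RCO and RCS against control, 772 in RCO against SWOP, 2976 in RCS against SWOP and 1073 in RCS against RCO. With only the 2 groups in the fit the counts were 4091 in SWOP and 564 in RCO against control, 863 in RCO against SWOP and 931 in RCS against RCO. Camera with the correlation estimated for each list called 0 lists in SWOP, RCO and RCS against control, 0 in RCO against SWOP, 0 in RCS against SWOP and 0 in RCS against RCO. Fry called 1 list in SWOP and 25 in RCS against control, 6 in RCO against SWOP and 23 in RCS against SWOP. Without the 2 arrays of high spike-in signal RCS against RCO gave 2951. Without RCO replicates 2 and 3 the counts were 1135 in RCO against control and 9052 in RCS against RCO, 9 lists were called in RCO against SWOP, and the oxidative phosphorylation list in RCO reversed to 0.11 (adjusted p = 0.22). Controls split 2 against 3, which leaves fewer controls in each comparison, gave median overlaps of 17 for SWOP and RCO, 98 for SWOP and RCS and 681 for RCO and RCS. Without single arrays SWOP against control ranged over 480–2023 (control replicate 2: 567, 4: 480, 5: 903; SWOP replicate 2: 660, 3: 856, 4: 528, 5: 670) and its lists over 3–6 (control replicate 4: 3). RCO against control ranged over 1323–4251 (control replicate 2: 1528; RCO replicate 3: 1323, 5: 4251), RCS against control over 9439–11417 and RCS against SWOP over 5430–7118. RCO against SWOP ranged over 1006–2988 (RCO replicate 3: 1376; SWOP replicate 2: 1093, 3: 1369, 4: 1375, 5: 1006), and RCS against RCO over 2053–7448 (RCO replicate 1: 2945, 2: 7448, 4: 3049, 5: 2410; RCS replicate 3: 2053). Lists ranged over 11–17 in RCO and 13–15 in RCS against control, 14–17 in RCO against SWOP, and 13–15 in RCS against SWOP and in RCS against RCO. With a replicate block the counts were 2119, 3061 and 11796 against control, 2860 in RCO against SWOP, 7434 in RCS against SWOP and 5275 in RCS against RCO. Per the labels the arrays share only a number. Deviations from the group means of same-numbered arrays correlated at a mean of −0.012 to 0.16 per number, and 10 of 20 arrays correlated best with their own number, where chance gives 4, a hint from the data and not the design.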

Other observations

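Single members of lists that camera did not call also differed in RCO or RCS. Fibroblast markers had 3 of 11 members higher in RCO against control (4 adjusted over the list alone, camera adjusted p = 0.085), among them the surface glycoprotein THY1 at 1.27 ± 0.26 and the calcium-binding protein S100A4 at 1.55 ± 0.38 (SE, n = 5 per group). In RCS S100A4 stood at 2.89 ± 0.38. Among antioxidant and late preconditioning effectors TXN rose by 1.45 ± 0.12 in RCS and GCLC, which limits glutathione synthesis, by 1.04 ± 0.12, while CAT fell by 0.91 ± 0.11, and in RCO 5 of 25 members rose and 1 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.68). The apoptosis list had 5 of 17 members higher in RCO (6 adjusted over the list alone, camera adjusted p = 0.058) and the hypoxia list 3 of 12 (3 and 1 lower adjusted over the list alone, camera adjusted p = 0.058). Fry called both of these lists in RCO (adjusted p = 0.0017 and 0.00025). In RCO the adjusted p of THY1 and S100A4 were 0.061 and 0.076 with only the 2 groups in the fit, and 0.054 and 0.070 without RCO replicates 2 and 3 (S100A4 at 0.84).

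The tests of dilution, of loss of cardiomyocytes and of array labels were chosen only after the result was seen, as were the fits without RCO replicates 2 and 3 and without the 2 arrays of high spike-in signal. The readings of the quantile, clock and glucocorticoid tests as open were also set after their values were seen. The first forces its outcome, and the other lists had only 3 of 14 and 6 of 8 genes measured. By the rule written beforehand, the clock value in SWOP (exact permutation p = 0.0476) would have counted for a different clock phase. The glucocorticoid value (exact permutation p = 0.5) would have counted against less glucocorticoid signalling.

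In SWOP and RCS calls were mostly lower among dim probe sets and higher among bright ones, 65.5 and 39.3 percentage points apart, with 35.5 in RCO against control, 42.5 in RCS against RCO, −2.57 in RCS against SWOP and −32.6 in RCO against SWOP. Quantile normalization brought SWOP and RCS to −5.62 and −0.553, but it forces equal distributions and brought all 6 comparisons to between −16.5 and 1.60, so it cannot tell a technical spread from a biological one. If the array response were steeper, the spike-ins would span a wider range. Their span differed from control by −0.09 ± 0.09 in SWOP (SE, exact permutation p = 0.389), which makes that unlikely there, although SWOP replicate 1 alone stood at 4.99 and the others at 5.25 to 5.40. In RCS it differed by 0.19 ± 0.06 (exact permutation p = 0.00794), so a steeper response may contribute to the RCS calls.

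In RCS 20 of 23 sarcomere and calcium handling genes fell while 8 of 14 macrophage markers rose, 1 fell and 5 did not pass, and both lists had an adjusted p = 0.42 with an estimated correlation in camera. The fetal gene program, also of myocytes, had 10 of 14 members higher. Dilution by added cells would lower all resident cell types alike, yet endothelial markers stood 0.49 (SD 0.33) above the sarcomere list relative to control (exact permutation p = 0.0159). In RCS replicate 1 these lists were level, at −0.38 and −0.41. Loss of cardiomyocytes alone would leave macrophage markers level with endothelial markers, and they stood 1.43 (SD 0.25) above them (exact permutation p = 0.00794). If expression per cell were unchanged, neither dilution alone nor loss alone would give these values. The limits for both were set after the list means had been seen, so the values are no independent test. Both together, or changes within cells, remain possible, as a hypothesis that staining and cell counts in the same tissue could test.

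RCO arrays spread between control and RCS. If RCO replicates 2 and 3 were RCS arrays under a wrong label, they should lie outside the range of 4 RCS arrays on no more of the 30 lists than an RCS array does. RCS arrays did so on 3 to 17 lists, RCO replicate 3 on 9.8 (a mean over the choices of 4) and RCO replicate 2 on 17.2, so a wrong label cannot be told apart from a real spread on this count. RCO replicate 2 fitted neither group in lymphocyte markers (0.44, other RCO arrays 0.02 to 0.13, RCS −0.32 to −0.19) or heat shock proteins (0.03, other RCO arrays 0.61 to 0.91, RCS 0.47 to 0.69), and TCN1, SMPDL3A and AMBN, with all 5 RCS arrays above every RCO array, were picked for that difference, so these values exclude nothing. A different response of these animals is a hypothesis that infarct or flow measurements could test.

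Clock genes not seen before, tested after ARNTL and PER1 had been noticed, had a signed mean difference (ARNTL phase minus PER phase) of 0.31 in SWOP (exact permutation p = 0.0476, 0.0952 adjusted), 0.51 in RCO (0.0714 adjusted) and 0.68 in RCS (0.0476 adjusted), with only 3 of 14 genes measured. Glucocorticoid-induced genes, of which 6 of 8 were measured, differed by −0.14 in SWOP (SD 0.16 in SWOP and 0.42 in control, exact permutation p = 0.5, 0.676 adjusted).

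With the arrays of 2 groups divided in 100 ways, the real one included, only that 1 reached the real count in SWOP against control (1716, highest other 178). The same held in RCS against control (11404, 495) and in RCO against SWOP (2414, 893), so a random division is an unlikely source of these counts. With the real one included, 1 of 100 is the smallest share possible. Wrong divisions mix the true groups, which widens the spread on each side and lowers their counts. The test also cannot tell the protocols from any other difference between the groups. In RCO against control (2571) and RCS against SWOP (6989) also only 1 of 100 reached the count, but in each 1 wrong division gave over 1000 calls. These were 1917 with control replicate 3 beside RCO replicates 1 to 4, and 1784 with SWOP replicate 1 beside RCS replicates 1 to 4. Each of these divisions is the real one with 1 array exchanged on each side, RCO replicate 5 in the first and RCS replicate 5 in the second. These arrays had the lowest scores of their groups on the first principal component, −18.3 and 26.4. Such a division keeps most of a group difference, so these counts need no other structure of the samples. They do not exclude chance for single calls. In the simulation with each group's own SD 31.2% of the RCO calls were false, 80 of 256. Far fewer probe sets were called there than the 2571 in the data, so that share does not carry over. In RCS against RCO 2 of 100 reached it, the real one (4572) and 1 with RCO replicate 2 beside RCS replicates 1 to 4 (6127). In that division RCO replicate 2, at 44 on the first principal component, took the place of RCS replicate 5, at 26.4. The share is under 5%, but a wrong division gave more calls than the real one and 4 exceeded 1000. The count therefore does not show that the labels divide these arrays best.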
